A study of Homo sapiens with 9 samples.

How the data were processed

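HCCLM3 cells, an established human hepatocellular carcinoma line, were transfected with a non-targeting control siRNA, siRNA against UXS1 or siRNA against MRPL42, with 3 libraries per group. Per the labels' protocols, mRNA was captured on beads, fragmented and reverse transcribed, and adapter-ligated cDNA was size selected and amplified by PCR. Whether the libraries keep the strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be assigned with certainty. Per the submitters' processing notes, fastp, Bowtie2, HISAT2, edgeR and the build hg38 were used. Their versions, roles and order, the annotation and the counting program are not given in the sources used here.

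The deposited table holds estimated counts per gene as the authors made them, not divided by depth or length. Of the values above 0, 83.6% to 84.9% per library were whole numbers, and the rest had decimals. A design written for raw counts was therefore run on estimated counts rounded to whole numbers. The table lists 20379 genes, of which 3866 had no count in any library and 646 no symbol. Another 9 columns, with TPM per library, were not used. Columns were assigned to groups by name only: the UXS1 siRNA columns carry the name with 2 letters exchanged, and no label ties the letters a, b and c to the repeat numbers. Library totals lay between 15265959 and 22400560. PCR reads without molecular identifiers are not independent molecules, so the counts overstate the number of molecules read. No pair of libraries agreed within counting noise (chi-square per gene of 3.37 or more in every pair), so none was merged as a copy of another. Repeat preparations of 1 culture could also exceed this noise, so it does not show separate cultures.

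Tests were run with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered by filterByExpr, scaled by TMM and fitted with 1 mean per group over all 9 libraries, so that the groups share the spread. The quasi-likelihood test was two-sided, and p-values were adjusted by Benjamini-Hochberg over the 12657 genes tested in each comparison, with a threshold of 0.05. CPM values use the total over tested genes adjusted by the TMM factor of each library, and are given as means ± SD over libraries. Both targets were also compared by an exact two-sided permutation test of CPM. The common biological coefficient of variation was 0.130 with all libraries and 0.0753 without control library c.

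A set of 36 gene lists was fixed before the data were examined. They cover glycosaminoglycan and nucleotide sugar metabolism, mitochondria, lipid and glucose metabolism, stress, cell cycle and signalling programs, ribosomal proteins, other cell types and RNA quality. Of 1179 list entries 1175 were in the table. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Benjamini-Hochberg adjustment was over the 36 lists of a comparison. Gene families sharing a symbol stem, and the pathway and gene ontology terms of the table, with 10 to 500 members each, were tested in the same way.

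Named genes follow a rule fixed in advance. It takes both targets. It takes the 10 largest rises and the 10 largest falls per knockdown among genes with an adjusted p below 0.05, at least 5 CPM in the higher group, all knockdown libraries on one side of all controls and a protein-coding symbol. From called lists and the lists nearest to the targets it takes up to 4 members past the threshold by size of change, or the 2 with the smallest p where none passes. From a named wider set it takes the 3 largest changes past the threshold. Its use on the fit without control library c, where 3 knockdown libraries face 2 controls, was decided after the data were seen. Coordinates come from the GENCODE 29 annotation of GRCh38, in which 20128 of the gene identifiers were found, 19733 of them protein coding.

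Transcript length was the median over the principal transcripts of a gene. This definition and the settings of the length-matched test (10000 random lists, 30 nearest genes per member, length weighted 3 times) were settled on simulated data before the test of the real lists, after earlier versions, among them one with the longest transcript, had failed there. The length correction used offsets per library from a lowess curve with a span of 0.3. The shared controls were simulated with 50 draws of unchanged groups.

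The gene test was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes among 12657. In the simulation of UXS1 siRNA against control siRNA it recovered 53.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and all of those changed 4-fold, with 13 false calls. In that of MRPL42 siRNA against control siRNA the shares were 49.3%, 76.1% and 93.9%, with 10 false calls. Between the knockdowns they were 47.8%, 85.1% and 93.9%, with 9 false calls.

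Alternatives fixed together with the lists were RLE size factors, library totals alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, a fit of the 6 libraries compared, an adjusted p below 0.01, a test against a fold of 1.2, an estimated correlation, and leaving out each library in turn. Chosen after the data were seen were the length correction, limma-voom with library weights, the legacy quasi-likelihood fit, leaving out control library c together with MRPL42 siRNA library b, a block on the column letters, and the wider sets without control library c. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.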

Results

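Poly(A) RNA was sequenced from HCCLM3 cells, a human hepatocellular carcinoma line, after transfection with a non-targeting control siRNA, with siRNA against UXS1 or with siRNA against MRPL42. UXS1 encodes UDP-glucuronate decarboxylase, the enzyme that makes UDP-xylose, from which the linker of glycosaminoglycan chains is started. MRPL42 encodes a protein of the mitochondrial ribosome. Each of the 3 groups had 3 libraries, named here by group and by the letters a, b and c, and the 9 libraries held between 15265959 and 22400560 estimated counts. Of the 20379 genes listed, 12657 passed the filter on low counts and were tested. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

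Control library c stood apart from the other 8 libraries. Across genes, which are not independent replicates, Pearson's r of its log2 CPM (counts scaled to the TMM-adjusted library total) with the other libraries lay between 0.956 and 0.967, while pairs among the other 8 libraries reached 0.985 or more. In control library c, 84 genes lay over 4-fold from both other control libraries, against 0 to 2 genes in each of the other 8 libraries by the same count. Hepatocyte genes were low there, with a mean relative log2 CPM over the list of -0.98, against 0.11 in control library a and 0.07 in control library b. NF-kB and inflammatory genes stood at -0.94 in control library c, against 0.01 and -0.07. The list of nuclear-retained and histone RNAs, kept as a sign of RNA quality, stood at 0.93 in control library c and at -0.51 and -0.38 in the other controls, while the 6 knockdown libraries lay between -0.09 and 0.05. Among single genes chosen after their values were seen, ADH1C, an alcohol dehydrogenase of the liver, had 23.7 CPM in control library a and no count in c. CDH17, an intestinal cadherin, had 137 and 145 CPM in a and b and 614 CPM in c. Both comparisons with control siRNA are therefore also given without control library c, a choice made after these values had been seen.

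The first question was whether each siRNA lowered its own target. UXS1 mRNA (chromosome 2, 106093303 to 106194339, minus strand, GRCh38) stood at 141 ± 3.43 CPM in UXS1 siRNA, 158 ± 18.8 CPM in control siRNA and 148 ± 7.76 CPM in MRPL42 siRNA (SD, n = 3 each). Its log2 fold change in UXS1 siRNA was -0.17 (SE 0.09, 95% confidence interval -0.36 to 0.03), with an edgeR adjusted p of 0.340. MRPL42 mRNA (chromosome 12, 93467488 to 93516213, plus strand) stood at 93.1 ± 11.3 CPM in MRPL42 siRNA, 122 ± 23.4 CPM in control siRNA and 124 ± 8.49 CPM in UXS1 siRNA (SD, n = 3 each). Its log2 fold change in MRPL42 siRNA was -0.39 (SE 0.14, 95% confidence interval -0.70 to -0.07), with an unadjusted p of 0.0203 and an adjusted p of 0.184 in edgeR. Its principal transcript is long (8251 bases, against a median of 2993 over genes). Per doubling of transcript length, log2 CPM changed by 0.05 to 0.13 in the controls and by -0.10, 0.04 and -0.08 in MRPL42 siRNA libraries a, b and c. Part of the MRPL42 change may therefore go with length. In UXS1 siRNA, where MRPL42 mRNA was not lower, the slopes were -0.07 to -0.01. The exact two-sided permutation test gave p = 0.2 for each target against control, where 3 libraries against 3 cannot go below 0.1. Between the knockdowns, MRPL42 mRNA was higher in every UXS1 siRNA library than in every MRPL42 siRNA library (log2 fold change 0.41, 95% confidence interval 0.10 to 0.73). The exact permutation p was 0.1, and edgeR gave an unadjusted p of 0.0145 and an adjusted p of 0.9996. The same contrast without control library c gave 0.41 (95% confidence interval 0.20 to 0.62), with an edgeR unadjusted p of 0.00148 and an adjusted p of 0.864. MRPL42 mRNA in UXS1 siRNA differed from control by 0.03, and UXS1 mRNA in MRPL42 siRNA by -0.10. Without control library c, which had the highest level of both mRNAs, the target changes were -0.08 for UXS1 and -0.24 for MRPL42. Neither target passed the adjusted threshold, so the libraries are named by their siRNA and not by a measured loss of its target.

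**Figure D1:**
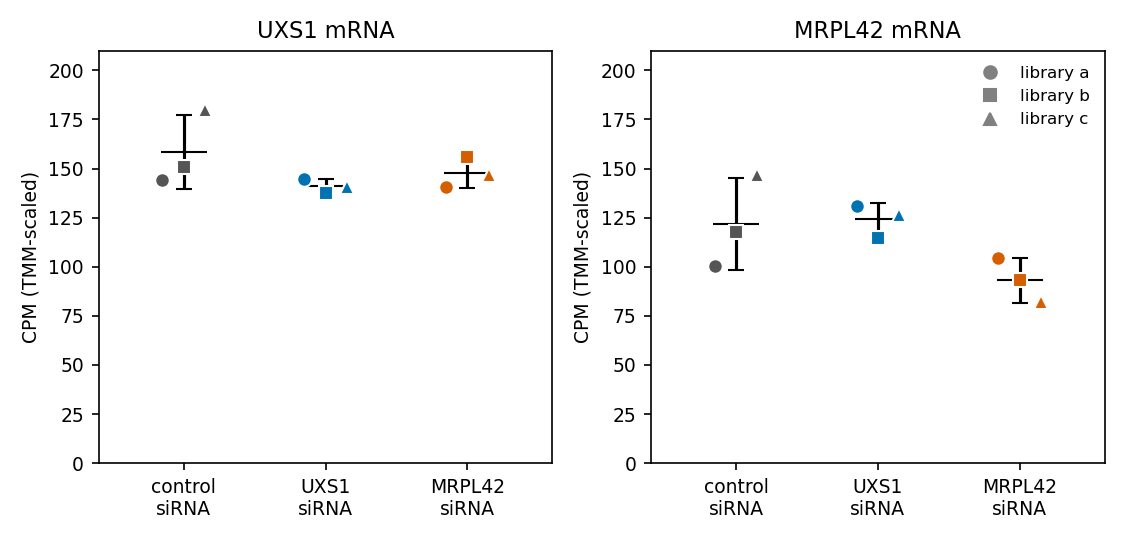
Level of UXS1 and MRPL42 mRNA in CPM (vertical axis) in each of the 9 libraries, grouped by siRNA. Points are libraries, horizontal lines are group means and bars are the SD (n = 3). UXS1 means were 158 (control siRNA), 141 (UXS1 siRNA) and 148 (MRPL42 siRNA), and MRPL42 means were 122, 124 and 93.1.

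In UXS1 siRNA against control siRNA, 2 genes passed the threshold and both fell. CPLX2, which encodes complexin 2, a regulator of vesicle exocytosis (chromosome 5, 175796310 to 175884020, plus strand), stood at 7.33 ± 0.113 CPM against 13.8 ± 0.853 CPM (SD, n = 3 each; log2 fold change -0.91, SE 0.09, edgeR adjusted p = 0.0295). STC2, which encodes the secreted glycoprotein stanniocalcin 2 and is a target of the integrated stress response (chromosome 5, 173314713 to 173329503, minus strand), stood at 57.9 ± 3.79 CPM against 103 ± 9.50 CPM (log2 fold change -0.83, SE 0.09, edgeR adjusted p = 0.0295). For both genes all 3 knockdown libraries lay below all 3 controls. Genes of cholesterol synthesis rose as a group, with 24 of 25 above 0 and a median log2 fold change of 0.36 (camera adjusted p = 2.02e-14, and adjusted p = 0.00436 with an estimated correlation). INSIG1, the sterol-regulated retention protein, stood at 179 ± 4.04 CPM against 119 ± 16.8 CPM (0.59, adjusted p = 0.111), and HSD17B7, an enzyme of the pathway, at 19.8 ± 0.736 CPM against 14.3 ± 0.266 CPM (0.47, adjusted p = 0.133). None of the 25 passed over all genes tested, and 16 did when adjusted over the list alone. Of the 36 lists, 12 were called, 10 up and 2 down. Cholesterol synthesis was the 1 list called with an estimated correlation.

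The 2 lists that fell were stress and early response genes. The integrated stress response list, the genes driven by ATF4 and CHOP, had a median of -0.39, with 39 of 42 members below 0 and STC2 past the threshold (camera adjusted p = 1.26e-14, and adjusted p = 0.277 with an estimated correlation). Adjusted over the list alone, 12 members fell. The median of this list was -0.23 without control library b and -0.24 without control library a, and the list was called in each of the 6 omissions of 1 library. AP-1 and immediate early genes also had a median of -0.39, with 25 of 27 below 0 (adjusted p = 2.46e-15, and adjusted p = 0.277 with an estimated correlation). DUSP5 and DUSP6, phosphatases induced by ERK signalling, had log2 fold changes of -0.45 (adjusted p = 0.0808) and -0.84 (adjusted p = 0.111), and 11 members fell when adjusted over the list alone. Control library c was the lowest library for the stress response list (-0.35, with 0.48 in a, 0.44 in b and -0.17 to -0.09 in UXS1 siRNA) and the highest for AP-1 genes (0.42).

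Genes of ribosomes and of the respiratory chain rose as lists. All 75 cytosolic ribosomal protein genes lay above 0, with a median of 0.59 (adjusted p = 3.6e-43, and adjusted p = 0.277 with an estimated correlation), and 72 rose when adjusted over the list alone. RPS26, whose reads may be shared with processed pseudogenes, stood at 370 ± 34.7 CPM against 185 ± 11.1 CPM (adjusted p = 0.106), and RPL24 at 275 ± 20.4 CPM against 184 ± 10.1 CPM (adjusted p = 0.155). Median changes were 0.37 for complex I, 0.43 for nuclear genes of complexes II to V and 0.25 for each subunit of the mitochondrial ribosome. For all 4 of these lists the adjusted p was 0.277 with an estimated correlation. Examples are NDUFA2 (1.03, adjusted p = 0.166), COX7B (0.86, adjusted p = 0.153), MRPL43 (0.61, adjusted p = 0.166) and MRPS33 (0.32, adjusted p = 0.156). Short transcripts outside these lists moved along: 626 genes with a transcript under 1000 bases had a mean relative log2 CPM of -0.20, -0.26 and -0.36 in the control libraries and between 0.03 and 0.21 in UXS1 siRNA. With a correction for transcript length in each library the cytosolic ribosomal protein median was 0.18, that of complex I 0.11 and those of the mitochondrial ribosome 0.04 (large subunit) and 0.06 (small subunit), all still called by camera with the preset correlation. MRPS33 turned direction under this correction.

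Of the remaining lists called, NF-kB and inflammatory genes had a median of 0.32 (adjusted p = 0.429 with an estimated correlation), fatty acid synthesis 0.21 (adjusted p = 0.353 with an estimated correlation), and DNA replication and mitosis genes 0.11 and 0.10 (adjusted p = 0.603 for both with an estimated correlation). NFKBIZ had a log2 fold change of 0.48 (adjusted p = 0.141), ACSS2 of 0.50 (adjusted p = 0.111), GINS2 of 0.42 (adjusted p = 0.176) and SPC24 of 0.56 (adjusted p = 0.111). The fit without control library c gave medians of 0.19 for NF-kB, 0.04 for fatty acid synthesis, 0.02 for replication and -0.01 for mitosis, the last pair no longer called (adjusted p = 0.582 and 0.753). The lists nearest to UXS1 itself were not called. The 23 measured enzymes of UDP-glucuronate, UDP-xylose and the glycosaminoglycan linker had a median of 0.03 (adjusted p = 0.998), with B4GALT7 at 0.20 (adjusted p = 0.333) and XYLT2 at -0.14 (adjusted p = 0.334). Heparan and chondroitin sulfate chain enzymes had a median of -0.15 (adjusted p = 0.112), with CHST15 at -0.31 (adjusted p = 0.176). Proteoglycan core proteins had a median of -0.08 (adjusted p = 0.116). Versican (VCAN) stood at 84.8 ± 4.33 CPM against 184 ± 126 CPM, a control spread set by library c. Mitochondrially encoded mRNAs had a median of -0.03 (adjusted p = 0.705).

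Leaving out control library c gave 203 genes in UXS1 siRNA against control siRNA, 64 higher and 139 lower, where the fit with all 9 libraries gave 2. Of the 42 stress response genes, 29 fell (median -0.52, camera adjusted p = 2.17e-79, and adjusted p = 0.0246 with an estimated correlation). ASNS, which encodes asparagine synthetase, stood at 111 ± 7.18 CPM (SD, n = 3) against a mean of 255 CPM (n = 2; log2 fold change -1.19, SE 0.10, edgeR adjusted p = 0.00104). ADM2 (-1.33), CHAC1 (-1.32), the glycine transporter gene SLC6A9 (-1.29), ALDH1L2 (-1.19) and SESN2 (-1.10) also fell, as did NIBAN1 (-1.33), the metallothionein gene MT2A (-1.17), TNS4 (-1.09) and the readthrough gene ARHGAP11A-SCG5 (-1.39), which overlaps its neighbours and is uncertain. In the cholesterol list 8 of 25 genes rose (median 0.30, adjusted p = 0.0075 with an estimated correlation), led by IDI1 (0.47), INSIG1 (0.46), FDFT1 (0.46) and HSD17B7 (0.45). Among AP-1 genes 9 of 27 fell, led by FOS (-0.65), DUSP6 (-0.64), EGR1 (-0.63) and ETV5 (-0.47), with adjusted p = 0.185 for the list with an estimated correlation. The largest single rises were SPANXD (1.15), RPS26 (1.03), the BMP target ID3 (0.90), RASL11A (0.88), LSM3 (0.87), AP1M2 (0.81), TOMM6 (0.73), TRIM31 (0.71), BOLA3 (0.66) and HHLA2 (0.66). SPANXD and RPS26 have near-identical copies that can share reads. HHLA2 stood at -0.40 with all 9 libraries, since control library c had 26.1 CPM against 5.62 and 6.47 in the other controls. Among proteoglycan cores VCAN fell (-0.41, adjusted p = 0.0213). The list of nuclear-retained and histone RNAs rose in this fit (median 0.35, adjusted p = 0.185 with an estimated correlation), with H2BC4 at 1.30 (adjusted p = 0.134) and H2BC12 at 0.35 (adjusted p = 0.126). So did the list of fibroblast, endothelial and leukocyte markers (median 0.13, adjusted p = 0.347 with an estimated correlation), in which the lysosomal gene CD68 rose (0.44, adjusted p = 0.00767).

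These counts depend on single libraries. Leaving out any 1 of the other 5 libraries of this comparison left 0 genes past the edgeR threshold. All 9 libraries gave 2 genes, with 2244 at an unadjusted p below 0.05, DESeq2 gave 453 and limma-voom 2. The balance of rises and falls turned with the fit. DESeq2 gave 311 higher and 142 lower, the 6 libraries compared 239 and 23, and library weights 873 and 442. Omitting control library c and MRPL42 siRNA library b gave 793 and 423. The length correction without control library c gave 127 and 189.

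In MRPL42 siRNA against control siRNA, no gene passed the edgeR threshold with all 9 libraries (lowest adjusted p 0.0894), although 2575 genes had an unadjusted p below 0.05, DESeq2 called 662 and limma-voom 0. Cholesterol synthesis genes rose as a list, with 24 of 25 above 0 and a median of 0.33 (camera adjusted p = 2.34e-14, and adjusted p = 0.00426 with an estimated correlation). HSD17B7 stood at 20.7 ± 1.77 CPM against 14.3 ± 0.266 CPM (SD, n = 3 each; log2 fold change 0.53, edgeR adjusted p = 0.131), and EBP, a sterol isomerase, at 244 ± 49.3 CPM against 145 ± 7.85 CPM (0.75, adjusted p = 0.131). In this list 15 members rose when adjusted over the list alone. The stress response list fell, with 39 of 42 below 0 and a median of -0.35 (adjusted p = 1.46e-09, and adjusted p = 0.417 with an estimated correlation), and the median was -0.21 without control library b. STC2 stood at 62.5 ± 4.17 CPM against 103 ± 9.50 CPM (-0.72, adjusted p = 0.0947) and the secreted stress factor GDF15 at 66.4 ± 7.72 CPM against 110 ± 12.8 CPM (-0.73, adjusted p = 0.131). Of the 36 lists 13 were called, 10 up and 3 down, and 1 with an estimated correlation.

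Genes of both ribosomes and of the respiratory chain rose as lists here too. Cytosolic ribosomal protein genes had a median of 0.63 with all 75 above 0 (adjusted p = 0.313 with an estimated correlation), and 72 rose when adjusted over the list alone. Complex I had a median of 0.48 and complexes II to V of 0.49 (adjusted p = 0.313 for both with an estimated correlation). The mitochondrial ribosome, to which MRPL42 belongs, had medians of 0.26 for the other 49 large subunit genes and 0.24 for the 32 small subunit genes (adjusted p = 0.339 and 0.313 with an estimated correlation). Examples are RPS27 (1.10, adjusted p = 0.133), NDUFS5 (0.57, adjusted p = 0.133), COX7B (0.92, adjusted p = 0.133), MRPL53 (1.15, adjusted p = 0.133) and MRPS12 (0.75, adjusted p = 0.133). MRPL42 siRNA library b stood apart in this group, with a mean relative log2 CPM of -0.21 for cytosolic ribosomal proteins, against 0.54 in library a and 0.30 in library c. The 626 short transcripts outside the lists stood at -0.13 in library b, against 0.35 and 0.20. Across genes, Pearson's r of MRPL42 siRNA library b was 0.992 with control library a and with control library b. It was 0.988 and 0.991 with MRPL42 siRNA libraries a and c. The knockdown libraries did not all group by siRNA: UXS1 siRNA library b was closest to MRPL42 siRNA library a (r = 0.995). With the transcript length correction the medians were 0.19 for cytosolic ribosomal proteins, 0.15 for complex I, 0.12 for complexes II to V, 0.08 for the large and 0.06 for the small mitochondrial subunit. NDUFS5 turned direction under this correction. Mitochondrially encoded mRNAs were not called (median 0.03, adjusted p = 0.774), with MT-CO3 at 0.16 (adjusted p = 0.280).

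AP-1 and immediate early genes fell as a list with a median of -0.34 (adjusted p = 0.313 with an estimated correlation), with DUSP6 at -0.80 (adjusted p = 0.131) and ETV5 at -0.34 (adjusted p = 0.133). The median was -0.13 without control library c, the highest library for this list. UDP-glucuronosyltransferases, which couple glucuronate to drugs and bilirubin, fell as a list with a median of -0.24 (adjusted p = 0.00214, and adjusted p = 0.313 with an estimated correlation). UGT1A8 had a log2 fold change of -0.29 (adjusted p = 0.137) and UGT1A1 of -0.22 (adjusted p = 0.137), but these genes share exons and their counts are uncertain. Glycolysis had a median of 0.13 (adjusted p = 0.313 with an estimated correlation) and was called in 3 of 6 omissions of 1 library. Its member ALDOA stood at 0.33 (adjusted p = 0.146), while SLC16A1 went the other way at -0.28 (adjusted p = 0.140). NF-kB genes had a median of 0.32 (adjusted p = 0.539 with an estimated correlation), with SAA1 at 2.20 (adjusted p = 0.139) on levels of 1.97 ± 1.03 against 0.423 ± 0.368 CPM. DNA replication and mitosis genes had medians of 0.12 and 0.08 (adjusted p = 0.721 and 0.758 with an estimated correlation). Neither was called without control library c (adjusted p = 0.178 and 0.754), and the NF-kB median was 0.12. The linker enzymes of glycosaminoglycans had a median of -0.01 (adjusted p = 0.973). UGDH, which makes UDP-glucuronate, stood at -0.22 (adjusted p = 0.190) and B3GAT3 at 0.28 (adjusted p = 0.215).

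Without control library c the comparison of MRPL42 siRNA with control siRNA gave 172 genes, 69 higher and 103 lower. Of 42 stress response genes 25 fell (median -0.45, adjusted p = 0.0408 with an estimated correlation). ASNS stood at 113 ± 16.6 CPM (SD, n = 3) against a mean of 255 CPM (n = 2; log2 fold change -1.18, SE 0.10, edgeR adjusted p = 0.00141). ADM2 (-1.37), NIBAN1 (-1.34), SLC6A9 (-1.26), ALDH1L2 (-1.10), the cystathionine enzyme gene CTH (-0.93), PSAT1 of serine synthesis (-0.92), IGFBP1 (-0.93), TXNIP (-0.92) and ARHGAP11A-SCG5 (-1.14) also fell. In the cholesterol list 12 of 25 rose (median 0.35, adjusted p = 0.00585 with an estimated correlation), led by EBP (0.70), HSD17B7 (0.53) and MVD (0.48). The largest single rises were FGFBP1 (1.44), SPANXD (1.07), RPS26 (0.99), ID3 (0.94), RASL11A (0.85), AP1M2 (0.84), LSM3 (0.79), TOMM6 (0.74), EBP (0.70) and ID1 (0.68). FGFBP1 stood at 0.27 with all 9 libraries. Nuclear-retained and histone RNAs rose here too (median 0.31, adjusted p = 0.294 with an estimated correlation), with H2BC4 at 1.57 (adjusted p = 0.0820) and H2BC5 at 0.52 (adjusted p = 0.197).

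The MRPL42 count also depended on single libraries. It was 796 genes without MRPL42 siRNA library b (736 higher and 60 lower). It was 0 when control library a, control library b, MRPL42 siRNA library a or MRPL42 siRNA library c was left out. Here too the balance turned with the fit. DESeq2 gave 512 higher and 150 lower, and library weights 1231 and 666. Omitting control library c and MRPL42 siRNA library b gave 1259 and 598. The length correction without control library c gave 130 and 156.

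The comparison of UXS1 siRNA with MRPL42 siRNA tests the difference between both knockdowns. The control libraries are on neither side of it, but they share in setting the spread of the fit. No gene passed the edgeR threshold, and 213 genes had an unadjusted p below 0.05, where chance would give 633. DESeq2 and limma-voom also called 0. Lists called were UDP-glucuronosyltransferases, higher in UXS1 siRNA with 12 of 14 above 0 and a median of 0.18 (camera adjusted p = 0.000676), AP-1 and immediate early genes, lower with 25 of 27 below 0 and a median of -0.10 (adjusted p = 0.000296), and YAP and TAZ targets, lower with a median of -0.05 (adjusted p = 0.0480). With an estimated correlation none was called (adjusted p = 0.513, 0.776 and 0.513). The cholesterol list differed between the knockdowns by a median of -0.05 (adjusted p = 0.709) and the stress response list by -0.06 (adjusted p = 0.0900). The YAP and TAZ list was called in 2 of 6 omissions of 1 library (adjusted p up to 0.643), the other 2 lists in all 6, with a UDP-glucuronosyltransferase median of 0.12 without MRPL42 siRNA library a and an AP-1 median of -0.16 without UXS1 siRNA library b. Leaving out MRPL42 siRNA library a, MRPL42 siRNA library b or UXS1 siRNA library b gave 10, 8 and 5 lists in place of 3. Without control library c no gene passed the edgeR threshold, and 684 genes had an unadjusted p below 0.05 (637 expected by chance). That fit called 7 lists, 2 higher and 5 lower in UXS1 siRNA, and none with an estimated correlation.

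**Figure D2:**
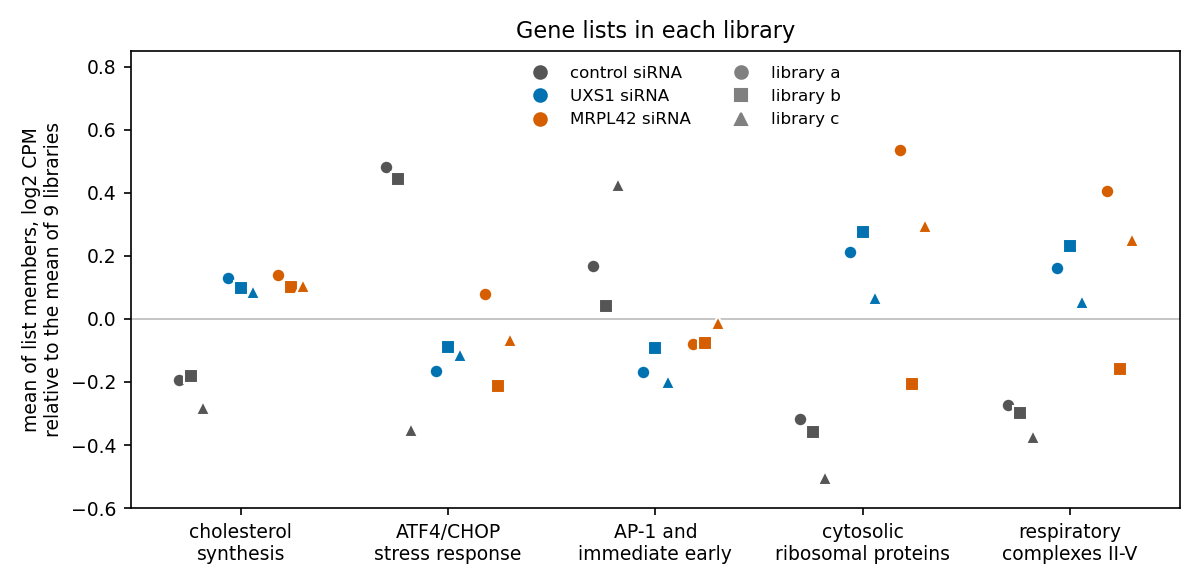
Mean relative log2 CPM of 5 gene lists (vertical axis) in each of the 9 libraries, grouped by siRNA; each point is a library. Cholesterol synthesis genes lay higher in all 6 knockdown libraries (0.09 to 0.14) than in all 3 controls (-0.28 to -0.18), and control library c lay apart from controls a and b for the stress response list (-0.35 against 0.48 and 0.44).

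The last comparison asked whether both knockdowns moved the same genes. With all 9 libraries no gene was called in both. When control library c was left out, 123 genes were called in both in the same direction, 39 up and 84 down, where independent lists of these sizes would share 0.346 and 1.12 genes. Both comparisons use the same control libraries, and 50 simulations of unchanged groups against them gave an overlap of 0.12 genes on average without control library c and 1 at most. The adjusted threshold calls few genes in unchanged groups, so this low overlap was largely set in advance. It does not test whether lists of 203 and 172 genes overlap through the shared controls. Across all genes tested, which are not independent replicates, Pearson's r of the log2 fold changes was 0.841 with all 9 libraries, against 0.493 in the simulations, and the covariance was 0.0987 against a simulated mean of 0.0258 and a simulated maximum of 0.0312. The fit without control library c gave an r of 0.781 against 0.594, and the covariance 0.0744 against 0.0231. The simulations drew each gene independently, with the same dispersion for a gene in every library. The 3 controls cannot be split so that each part keeps 2 libraries, so part of the excess may come from the shared controls.

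**Figure D3:**
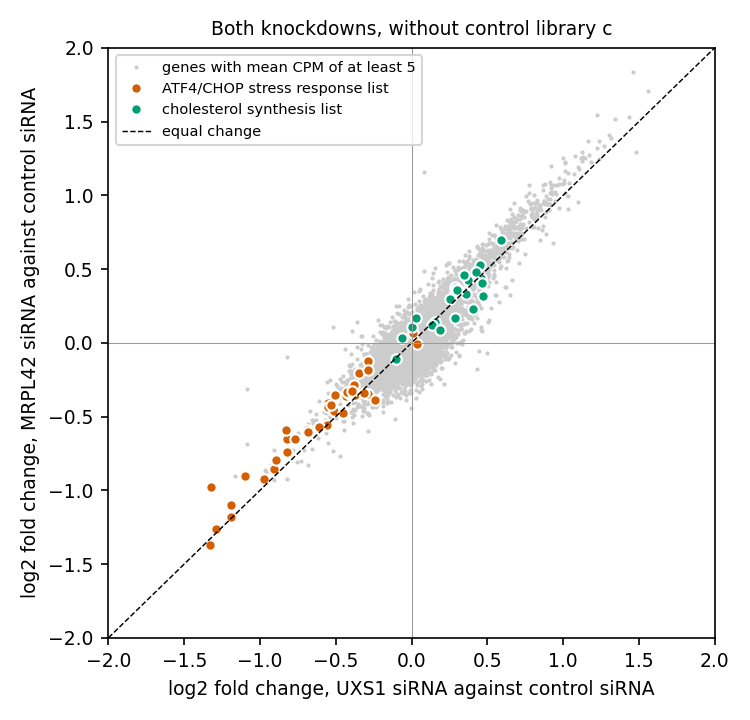
Log2 fold change in UXS1 siRNA (horizontal axis) and in MRPL42 siRNA (vertical axis), both against control siRNA and without control library c, for 10553 genes with a mean of at least 5 CPM; each point is a gene. Stress response genes (median -0.52 and -0.45) and cholesterol synthesis genes (median 0.30 and 0.35) are coloured.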

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

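The tests of control library c and of a state of the control cultures were chosen after the result was seen, while the length, shared-control and regrouping tests were written down before theirs. The difference between the knockdowns was tested for every list. Without control library c 7 lists passed with the preset correlation, and with all 9 libraries 3 did. UDP-glucuronosyltransferases were higher in UXS1 siRNA than in MRPL42 siRNA by a median of 0.18, AP-1 and immediate early genes were lower by a median of -0.10 (-0.0960 before rounding), and YAP and TAZ targets were lower by a median of -0.05 (-0.0549 before rounding). None was called with an estimated correlation. Of the 10 splits of these 6 libraries, 8 gave 3 or more lists, the real one included, and the highest other gave 8. For genes the real split and the highest other both gave 0, as did all 10 splits. With 10 splits a share under 0.05 cannot be reached.

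The same holds for the comparisons with control siRNA. For UXS1 siRNA the real split gave 2 genes and the highest other 0 (1 of 10 splits as large), and 12 lists against 18 (6 of 10 splits as large). For MRPL42 siRNA it gave 0 genes and the highest other 0 (10 of 10 splits as large), and 13 lists against 15 (3 of 10 splits as large).

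Control library c is the first pattern. Reads of other cells mixed in at less than 50% of the library could lower no abundant gene by over 2-fold, yet 35 of 7578 genes lay over 4-fold below both other controls, 4 of them over 16-fold. A swap with a knockdown library needs a library that resembles them, but its mean r with the 6 knockdown libraries was 0.962, below the lowest r between 2 knockdown libraries (0.988). A culture in another state and a sample of another origin both predict many genes apart. The 84 genes found cannot be told apart between these, since no second library of either kind exists here.

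The second pattern is the rise of ribosomal and respiratory mRNAs in both knockdowns. A trend with transcript length between libraries may account for part of it, since correction brought the cytosolic ribosomal protein median in UXS1 siRNA from 0.59 to 0.18. Genes of matched length rose less than the lists did. Cytosolic ribosomal proteins exceeded 10000 lists matched on length and expression by 0.28 (log2, the smaller of both knockdowns), and the mitochondrial ribosome and respiratory lists by 0.14, both above the central 95% of matched lists. That range takes list members as independent, and none of these lists was called with an estimated correlation. It therefore does not settle whether length alone is enough. The list kept as a sign of RNA quality moved too, with medians of 0.35 and 0.31 without control library c but of -0.22 and -0.31 with it and no call, so a difference in RNA quality stays open beside a biological reading.

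The third pattern is higher cholesterol synthesis and lower stress response genes in both knockdowns. Length correction left at least 0.923 of each list median without control library c, which argues against a length trend. Over all genes tested, chance shared through the same controls gave a covariance of at most 0.0312 in simulations, below the 0.0987 observed. The simulations drew each gene independently, with the same dispersion for a gene in every library. Control library c had a limma-voom weight of 0.102, against 0.512 to 2.55 in the others. Noise shared between genes, or larger in control library c, is therefore not covered. The covariance is over all genes and does not test these lists. A state of the control cultures, such as stress in controls a and b, and a common effect of both siRNAs cannot be told apart: 0 of 67 genes of both lists differed between the knockdowns, which either predicts. An effect of losing UXS1 or MRPL42 itself was not tested, and the target changes without control library c were -0.08 and -0.24.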

How the results depend on the processing

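The length correction, the library weights, the legacy fit, the block on letters and the omission of control library c together with MRPL42 siRNA library b were chosen after the result was seen. The planned replicate block on repeat numbers was not run, since no label ties the column letters to them. A replicate block on the letters a, b and c gave 0 genes in each comparison, where the fit without it gave 2, 0 and 0, and 13, 14 and 2 lists. Same-letter libraries did not deviate together: 2 of 9 pairs had a correlation over 0.1 (range -0.27 to 0.13), and 1 of 9 libraries lay closest to its own letter. A count was taken as the same within 1.5-fold of the main count. A fold change or list was taken as the same where its direction and its side of the threshold held, whatever its size. Of 168 alternative values of the main results, 129 were the same by this rule and 39 moved. Of 2906 alternative values of named genes and called lists, 2389 were the same, 411 became called, 73 lost their call and 33 turned direction. Medians of all genes shifted by under 0.02 under each scaling. The cause of the changes below was not tested, except that a stricter threshold can only lower a count. In simulated data 53.7%, 49.3% and 47.8% of genes changed 1.5-fold were recovered in the 3 comparisons, so small changes can be missed with 3 libraries per group.

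Genes called in UXS1 siRNA against control siRNA numbered 2, with 6 by library totals alone, 453 by DESeq2, 262 with the 6 libraries compared, 12 with the length correction, 1315 with library weights, 1216 without control library c and MRPL42 siRNA library b, 0 at an adjusted p below 0.01 and 0 against a fold of 1.2. Leaving out 1 library gave 0 to 203. In MRPL42 siRNA against control siRNA the count was 0, with 3 by library totals alone, 662 by DESeq2, 4 with the length correction, 1897 with library weights and 1857 without both libraries. Leaving out 1 library gave 0 to 796. Between the knockdowns the count was 0, and 1 without both libraries, a gene with no symbol. The overlap of both responses was 0, with 3 by library totals alone, 356 by DESeq2, 4 with the length correction, 960 with library weights, 993 without both libraries and 0 to 340 with 1 library left out.

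With an estimated correlation 1, 1 and 0 lists were called in place of 12, 13 and 3. Between the knockdowns 7 lists were called with the 6 libraries compared, 7 with library weights and 7 without both libraries. There were 7 without control library c, and 2 to 10 with 1 knockdown library left out. The target changes kept their sign, at -0.23 to -0.08 for UXS1 and -0.51 to -0.24 for MRPL42 with 1 library left out.

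Those that turned direction were these. The list of mitosis and G2/M genes, MRPL42 siRNA against control siRNA, stood at -0.0486 without both libraries. The length correction gave, in UXS1 siRNA, MT-CO3 -0.28, MRPS33 -0.0877 and H2BC4 -0.12, and in MRPL42 siRNA MT-CO3 -0.25, MT-ND3 -0.55, NDUFS5 -0.0440, MT-CO2 -0.45, MRPS33 -0.16 and H2BC5 -0.44. Library weights gave HHLA2 0.60, PAPSS2 0.15, H2BC12 0.32 and CD44 0.16, and the omission of both libraries gave HHLA2 0.66, PAPSS2 0.14, H2BC12 0.35 and CD44 0.15. With 1 library left out, MRPL42 in UXS1 siRNA ran from -0.0925 to 0.17, HHLA2 from -0.76 to 0.66, PAPSS2 from -0.16 to 0.15, CD68 from -0.0370 to 0.44, H2BC12 from -0.44 to 0.35, FGFBP1 from -0.12 to 1.44, CD44 from -0.26 to 0.20, MT-CO2 from -0.0497 to 0.17 and H2BC5 from -0.0815 to 0.52.

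List medians near 0, or of lists not called, also crossed 0 with 1 library left out, and not all are given here. For example, the mitosis and G2/M median in UXS1 siRNA ran from -0.00990 to 0.16, and that of linker enzymes from -0.0144 to 0.0535. Mitochondrially encoded mRNAs ran from -0.11 to 0.0577 in UXS1 siRNA and from -0.0615 to 0.0863 in MRPL42 siRNA, and nuclear-retained and histone RNAs from -0.44 to 0.35 and from -0.56 to 0.31.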

Other observations

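The wider gene sets without control library c were examined after the result was seen. In that fit, genes of aminoacyl-tRNA biosynthesis were lower in both knockdowns as a set (camera adjusted p = 3.3e-07 in UXS1 siRNA and 1.5e-06 in MRPL42 siRNA), with 10 of 44 members past the threshold in each. GARS1, which encodes glycyl-tRNA synthetase, fell by 0.69 in UXS1 siRNA and 0.59 in MRPL42 siRNA, and MARS1, which encodes methionyl-tRNA synthetase, by 0.65 and 0.54. With an estimated correlation the adjusted p was 0.65 and 0.66. Amino acid transport genes also fell as a set, with SLC7A1 at -0.68 and -0.60 and SLC38A1 at -0.45 and -0.53. In glycine, serine and threonine metabolism 6 of 28 genes fell in each knockdown, among them CTH (-0.98 and -0.93), PSAT1 (-0.97 and -0.92) and CBS (-0.90 and -0.86). CBS was also low in control library c, at 7.53 CPM against 38.6 and 36.2 CPM in the other controls. With all 9 libraries 5 pathways and 5 gene ontology processes were called lower in MRPL42 siRNA, and none of these sets was among them. The related function amino acid transmembrane transporter activity was called there (median -0.20). GARS1, SLC7A1, CTH, PSAT1 and CBS are also members of the stress response list, so these sets are not independent of it. Set calls were absent with an estimated correlation for every wider set tested.

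KLF transcription factors were lower in both knockdowns as a gene family with all 9 libraries (medians of -0.30 and -0.31 over 12 genes). Their medians were -0.23 and -0.18 without control library c. That fit had KLF4 (-0.43), KLF9 (-0.30) and KLF6 (-0.28) past the threshold in UXS1 siRNA and none in MRPL42 siRNA, but the difference between the knockdowns was not significant for any of the 3 (adjusted p = 0.864, 0.961 and 0.864).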
